A study of Homo sapiens with 20 samples.

How the data were processed

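RNA-seq was run on human islets 48 hours after transduction with an adenovirus for GFP or ASF1B, in 20 libraries from 10 islet preparations of 9 donors. Groups and preparations were taken from the sample titles. Both deposited tables give 1 column per library, and 0 per-sample columns could not be matched to a sample. Bowtie, RSEM and the build hg19 are named in the submitters' processing notes, and versions and annotation are not given in the sources used here. Strand handling is not given in the sources used here either.

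The values of the table of all genes are a normalized signal, deposited by the authors, and per the file headers they come from RSEM gene results. From the values, they are expected counts divided by 1 factor per library. These factors differ by 0% (to 3 decimals) from median-of-ratios factors computed from the whole table. The value of 1 read was read from the commonest low value of each library and lay between 0.556 and 1.44. Of the low values, up to 20 reads, between 92.2% and 93.6% per library were whole within 0.1 read, so the values were not treated as whole counts and no count model was run. Dividing by this step gave the depth, 9944379 to 24020836 expected reads per library, which limits what low genes can show. The authors' deposited table of comparisons gives a score for each gene named PPDE, per the file headers, which is 0.95 or above for every listed gene. It also gives the ratio or fold of the group means, its log2 value and a p-value, as deposited by the authors. The deposited p-value equals an unpaired 2-sample Student calculation for 464 of 464 genes, within a relative tolerance of 1e-06.

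The table holds 18969 genes, of which 1067 are at 0 in every library and 26 carry calendar dates in place of symbols, as spreadsheet software writes them. The 46 sex-linked genes were left out of every test. Of the symbols, 18799 were found in the GRCh38.p14 RefSeq gene table and 170 were not. That assembly differs from the authors' build, so it was used only for names and for which genes are neighbours, and no coordinates are given.

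The test fixed before the data were examined was a count model on expected counts rounded to whole numbers, with limma on log2 values as the stated fallback for a normalized unit. The fallback was used. Genes with a value of at least 10 in at least 10 libraries were kept, and log2(value + 1) was fitted in limma 3.58.1 under R 4.3.3 with group and islet preparation as terms and trended moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The block was the main design because the series text says that each preparation was divided between the viruses. The pairing was checked on deviations from the group means without ASF1B. Libraries of the same preparation correlated with r between 0.567 and 0.939 (median 0.851, 10 pairs), against -0.751 to 0.852 (median -0.0814) for 90 pairs of different preparations. The ranges overlap. Of the 90, the 2 pairs from 1 donor gave 0.808 and 0.852, and the 88 pairs of different donors -0.751 to 0.797 (median -0.0945). The 2 preparations of 1 donor differed by 4.24 times counting noise in GFP and 2.25 times in ASF1B (other pairs at least 7.95 and 7.12 times), so they were the most alike of all pairs and are not independent donors. They were kept as separate preparations, as the labels give them, and a fit with 9 donors was an alternative that used the mean of the donor's values in place of their sum.

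The rule for the genes named was written with that design. They are ASF1B, ASF1A, MKI67, INS and GCG, and, among called genes with the sign of the fit in at least 9 preparations and a mean of at least 1 CPM, the 10 largest rises and 10 largest falls. Up to 4 members of each gene list with the smallest p were added, and the texts name some of these. Some genes that the rule takes are not reported here. RFPL2, the genes of the run on chromosome 19 other than ZNF77, and members of lists beyond the first 4 were named after their values were seen, as were IAPP, SLC2A2 and KLK1. Of 29 lists written beforehand, 28 had at least 3 tested members. The mitochondrially encoded list had none in the table and was not tested. Lists were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and fry. The lists were tested on the log2 values, not on voom values as first written, because of the unit.

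The gene test, camera and fry were tested on simulated data, drawn from the GFP values with each gene's own spread between preparations (median dispersion 0.00615) and 200 changed genes. Over 14002 simulated genes of the ASF1B against GFP comparison, 52% of genes changed by 1.25-fold, 73.5% of those changed by 1.5-fold, 96% by 2-fold and 100% by 4-fold were called, and 3.07% of calls were false. The false share rests on 5 calls. Only 200 genes were changed, against 4821 called in the data, so these shares may not carry over to the data. A shift planted in 1 list was called, and 0 of 27 other lists were, also with an estimated correlation. Fry called it and 4 others, 3 of which held a changed gene. The simulation draws genes independently. It therefore tests neither the false share of gene calls when genes move together nor how camera behaves when the genes of a list do. The other statistics were tested on differences drawn with each gene's own spread, again independently between genes. Over 14158 genes, sign flips called any list in 0% of 200 simulations with no change. They called 1 list raised by 0.5 in 15%, since the smallest p they give passes the adjustment only when another list is low too, and 3 raised together in 100%. The test for unequal changes, on 22 genes, called a list falling alike in 7% and members differing by 0.6 in 100%. The class difference was called in 4% with no change and in 100% with a rise of 0.13. Its simulated class was drawn at random from all genes that passed the filter, so these shares may not hold for low genes that move together. Over 14014 genes in order, a run of neighbours was called in 0% of 20 simulations with no change, and a run raised by 0.7 was called and found in place in 100%. On counts drawn from 1 library's values, thinning left a difference of -4.6 detected genes between depths in a ratio of 0.6, of 18922 genes, and one of 192.5 with 200 genes added. The label swaps, which refit the tested model, had no simulation of their own.

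Alternatives written beforehand were the fit without the block, 9 donors, other scalings, other filters, voom, other thresholds and leaving out each preparation. TMM factors, pseudocounts of 0.5 and 10, robust moderation and the sign-flip test of lists were added after the data were seen. Versions over 9 donors of the sign-flip tests and label swaps, swaps of 1 preparation at a time, camera with an estimated correlation for each left-out preparation, 2 scalings and no filter, and the run of neighbours chosen without each donor were added then too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.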

Results

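Gene expression was measured by RNA-seq in 20 libraries of human pancreatic islets. The islets came as 10 preparations from 9 donors. Each preparation was divided into one portion that received an adenovirus carrying GFP and one that received an adenovirus carrying the histone chaperone ASF1B. RNA was taken 48 hours after transduction, which gave 10 GFP and 10 ASF1B libraries. GFP is a fluorescent protein and served as the control for the virus. ASF1B carries histones H3 and H4 to the complexes that deposit them on DNA. Islets hold endocrine cells, among them beta cells that secrete insulin and alpha cells that secrete glucagon, together with remnants of exocrine, vascular and connective tissue. The depth recovered from the deposited values ranged from 10780521 to 17328632 expected reads in the GFP libraries (median 14180952) and from 9944379 to 24020836 in the ASF1B libraries (median 14138056). Values below are normalized expected counts, and a change is the fitted log2 difference, ASF1B minus GFP, on the log2(value + 1) scale, which understates the change of low genes. Errors of a change are limma's moderated SE from the fit over the 10 preparations. That SE draws each gene's spread toward that of genes at a similar level, so it is not the plain SE of the 10 differences. Adjusted p values are limma's moderated test with Benjamini-Hochberg adjustment and the islet preparation as a block.

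ASF1B itself was read first in every library. Its normalized expected count lay between 310154 and 847974 in the 10 ASF1B libraries (mean 604741 ± 169224 SD, n = 10). In the GFP libraries it was below 25 in 9 of 10, with a lowest value of 10.2, and reached 159 in the GFP library of preparation 10. The change was 14.87 ± 0.31 (adjusted p = 3.49e-14), with within-preparation differences from 11.73 to 16.21. An exact two-sided sign-flip permutation test over the 10 preparations gave p = 0.002, and over the 9 donors p = 0.00391, each the smallest it can give. ASF1B took 4.31% ± 1.17 (SD, n = 10) of all expected reads in the ASF1B libraries and at most 0.0012% in the GFP libraries. ASF1A, the paralog of ASF1B, had a change of 0.21 ± 0.08 that did not pass (adjusted p = 0.0603). Without preparation 1, 5 or 6-1 in turn, the ASF1A change passed (adjusted p = 0.0251, 0.0333 and 0.04).

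**Figure D1:**
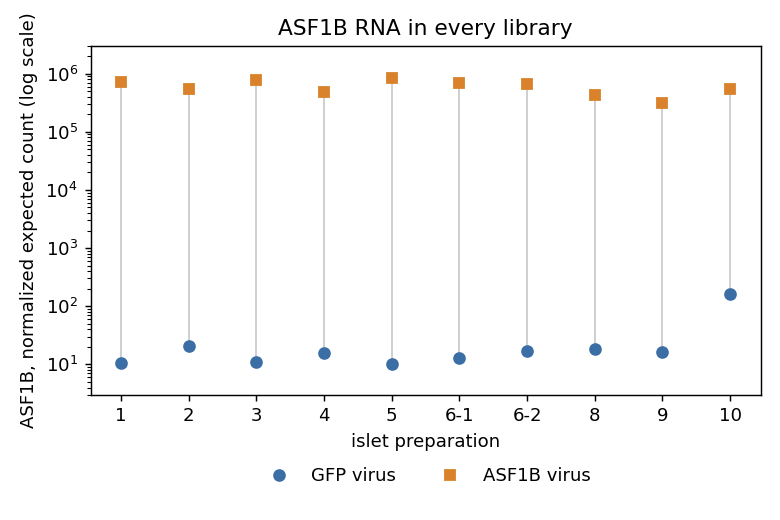
ASF1B normalized expected count (log axis) in each library, by islet preparation, for the GFP virus (circles) and the ASF1B virus (squares), with a line joining the libraries of a preparation. The ASF1B libraries sit between 310154 and 847974, and the GFP libraries below 25 except for 159 in preparation 10.

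The first comparison asked which genes differed between the ASF1B and GFP portions of the same islets. The neuronal transcription factor gene NHLH2 had the largest rise after ASF1B itself among the tested genes, from a mean of 4.28 to 93.4 (change 4.08 ± 0.23, adjusted p = 5.11e-08). The neurofilament genes NEFL and NEFM, which encode structural proteins of axons, rose by 3.89 ± 0.28 and 1.94 ± 0.12. ZNF77, a zinc finger gene, rose by 2.08 ± 0.13, the protocadherin gene PCDH8 by 2.22 ± 0.38 and KBTBD10, now named KLHL41, by 1.88 ± 0.21. NR1D1, which encodes a nuclear receptor of the circadian clock, rose by 1.83 ± 0.15, and BBC3, which encodes the pro-apoptotic protein PUMA, by 1.73 ± 0.31. RGPD6 rose by 2.39 ± 0.47, but it belongs to a family of near-identical copies, so its reads cannot be assigned with certainty. Falls were smaller. The largest among genes with a mean of at least 1 CPM were in TRPM5, a cation channel gene, at -1.23 ± 0.20, the lipase-related gene PNLIPRP1 at -0.998 ± 0.216 and GPR123, now named ADGRA1, at -0.98 ± 0.14. CAMK1G (-0.95 ± 0.23), PNLIP (-0.94 ± 0.23), TMEM130 (-0.88 ± 0.11), SERPINI2 (-0.87 ± 0.22), ECEL1 (-0.86 ± 0.13), RGS9 (-0.84 ± 0.10) and MCHR1 (-0.84 ± 0.15) completed the 10 largest falls. Of these 19 genes other than ASF1B, each had the sign of its fit in at least 9 of the 10 preparations. A pseudocount of 10 brought the change of NHLH2 to 2.66, of RGPD6 to 1.60, of PCDH8 to 1.05, of TRPM5 to -0.77, of CAMK1G to -0.62 and of SERPINI2 to -0.41. With voom, the falls of PNLIPRP1, PNLIP and SERPINI2 were -0.55, -0.58 and -0.55.

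In all, 4821 of 14158 tested genes (34.1%) were called at an adjusted p under 0.05, 2179 higher and 2642 lower in ASF1B. The counts of called list members below are to be read beside that share. Most changes were small, with a median fold of 1.19 among the called genes. A change of at least 2-fold was seen in 83 genes that were higher and 2 that were lower, TRPM5 and RFPL2. RFPL2, named after its value was seen, was at -1.01 ± 0.34 (adjusted p = 0.0311), and lost its call without preparation 1, 2, 4 or 9 in turn (adjusted p up to 0.0748) and with voom (0.0646). A pseudocount of 10 put it at -0.44. Without the block for the islet preparation, limma called 496 genes, 300 higher and 196 lower, all of them among the 4821. All 10 largest falls, RFPL2 (adjusted p = 0.38) and RGPD6 (adjusted p = 0.0569) then lost their call. Preparation 1 stood apart from the rest. Without it 5694 genes were called, and its own difference had the sign of that fit in 49.9% of those other than ASF1B. For each of the other preparations, compared in the same way, that share lay between 83.3% and 92.8%. The share of calls that were higher was 45.2%, and 57.0% when libraries were scaled to their totals without ASF1B, so the balance of small rises and falls depended on the scaling.

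**Figure D2:**
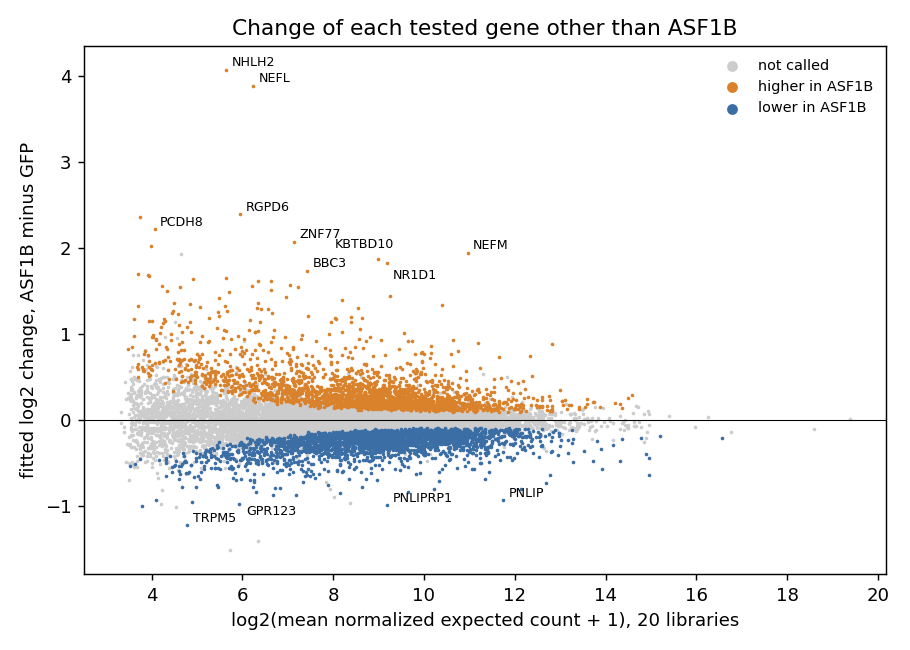
Fitted log2 change (ASF1B minus GFP) against log2 of the mean normalized expected count plus 1 for each tested gene other than ASF1B, with genes called higher in orange, lower in blue and not called in grey. The named rises reach 4.08 for NHLH2, while the named falls reach -1.23 for TRPM5.

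Target genes of p53, the transcription factor that responds to DNA damage, rose together. All 27 members of the list were called higher, over all genes tested and adjusted over the list alone, with a median change of 0.65. TRIAP1, an inhibitor of apoptosis, went from 326 to 890 (1.44 ± 0.09, adjusted p = 1.66e-07). FAS, a death receptor gene, rose by 1.18 ± 0.11, the DNA repair gene DDB2 by 0.85 ± 0.08 and the translesion polymerase gene POLH by 0.93 ± 0.09. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.88 ± 0.10, from 5122 to 9264. The median difference of the list was above 0 in 10 of 10 preparations. Camera with a preset correlation gave an adjusted p of 7.57e-22, and with an estimated correlation the adjusted p was 0.366.

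Of 42 tested G1/S and S phase genes, 17 were higher, 1 was lower (UBR7, -0.22 ± 0.04) and 24 were not called, with the same counts adjusted over the list alone. PCNA, the sliding clamp of DNA polymerase, rose by 0.66 ± 0.06, MCM7 of the replicative helicase by 0.60 ± 0.06, TYMS, which makes thymidylate, by 1.61 ± 0.18 and the licensing factor gene CDT1 by 1.32 ± 0.16. The list had a median change of 0.23 (camera adjusted p = 1.7e-05, and adjusted p = 0.738 with an estimated correlation). Of 46 G2/M and mitosis genes, 4 were higher, 4 lower and 38 not called (adjusted over the list alone, 2 higher and 4 lower), with camera's adjusted p at 0.828. SMC4 of condensin rose by 0.38 ± 0.07, and KIF20B, CKS2 and PSRC1 were also higher. HMGB2, LBR and G2E3 were lower, at -0.41 ± 0.05, -0.24 ± 0.05 and -0.29 ± 0.06, as was CDK1. CKS2 lost its call without preparation 2, 3, 4 or 6-2 in turn (adjusted p up to 0.0761), and PSRC1 without 2, 4, 5, 6-2, 8 or 9 (up to 0.0705). MKI67, a marker of cycling cells, had a change of -0.24 ± 0.17 that did not pass (adjusted p = 0.318). Among 14 cyclins and cyclin-dependent kinases, 2 were higher, CDK2 (0.57 ± 0.09) and CDK4 (0.17 ± 0.04), and 2 were lower, CCND2 (-0.17 ± 0.05) and CDK1 (-0.47 ± 0.15), also when adjusted over the list alone (camera adjusted p = 0.699). CDK1 lost its call without preparation 10 (adjusted p = 0.0583). Of 13 cell cycle inhibitors, 6 were higher and 3 lower, also adjusted over the list alone. BTG2 rose by 0.65 ± 0.13 and RBL1 by 0.72 ± 0.10, while RBL2 was lower at -0.33 ± 0.06, with CDKN2D and CDKN1B (camera adjusted p = 0.0797). Without the block for the preparation, every G2/M gene and cyclin or kinase named as called here, RBL2, CDKN2D and CDKN1B lost their calls (HMGB2 had the smallest adjusted p, 0.0584).

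Of 55 replication-dependent histone genes in the table, 10 passed the filter, and 9 of these were called higher and none lower (10 higher when adjusted over the list alone). HIST1H2BK went from 214 to 536 (1.31 ± 0.09, adjusted p = 6.46e-07), HIST1H2BD rose by 0.91 ± 0.08, HIST1H1C by 1.14 ± 0.13 and HIST2H2AA3 by 1.02 ± 0.14. Histone genes of a cluster share much of their sequence, so values of single copies are uncertain. The list's median change was 0.86 (camera adjusted p = 8.98e-08, and adjusted p = 0.366 with an estimated correlation), and 0.24 with no filter on low genes. Among 10 replication-independent variants, 5 were higher and 2 lower, also adjusted over the list alone, with H2AFZ at 0.43 ± 0.04 and the lower ones H2AFV at -0.31 ± 0.05 and H2AFY2 at -0.17 ± 0.05 (camera adjusted p = 0.0883). Of 30 other histone chaperones and their partners, 6 were higher and 5 lower (6 and 6 adjusted over the list alone), among them SUPT6H at 0.27 ± 0.05, DNAJC9 at 0.33 ± 0.07, ANP32E at -0.45 ± 0.06 and UBN2 at -0.31 ± 0.05. ANP32A, CDAN1 and NAP1L1 were also lower. CDAN1 lost its call without preparation 2, 3 or 9 in turn (adjusted p up to 0.0622), and NAP1L1 without 2, 4, 5, 6-1, 6-2, 9 or 10 (up to 0.0884). Without the block, H2AFV, H2AFY2, DNAJC9, ANP32A, CDAN1 and NAP1L1 lost their calls (adjusted p = 0.0672, 0.218, 0.0728, 0.292, 0.157 and 0.356). The median change of the chaperone list was -0.01 and its mean 0.00, and the median was 0.02 when libraries were scaled to totals without ASF1B (camera adjusted p = 0.873).

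Among called genes of endocrine and exocrine cells, those of acinar cells and of insulin secretion were lower and those of alpha cells higher. INS, the insulin gene, and GCG, the glucagon gene, did not pass, with changes of -0.11 ± 0.11 (adjusted p = 0.464) and 0.01 ± 0.10 (adjusted p = 0.94). Of 26 genes of the insulin secretion machinery, 18 were lower and none higher, also adjusted over the list alone. ABCC8, a subunit of the ATP-sensitive potassium channel, was at -0.58 ± 0.10, and the exocytosis genes VAMP2 and SYT7 were at -0.32 ± 0.05 and -0.37 ± 0.07. The median change of the list was -0.20 (camera adjusted p = 3.5e-05, and adjusted p = 0.738 with an estimated correlation). Of 22 beta cell genes, 7 were lower and 1 higher (9 and 1 adjusted over the list alone), with SLC2A2, a glucose transporter gene, higher at 0.35 ± 0.10 and ERO1LB at -0.47 ± 0.10, ADCYAP1 at -0.46 ± 0.09, SLC30A8 at -0.39 ± 0.09 and GLP1R at -0.42 ± 0.10. Camera's adjusted p for beta cell genes was 0.0674. It was 0.000537, 0.0412 and 0.0297 without preparation 1, 6-1 or 10 in turn (adjusted p = 0.514, 0.862 and 0.804 with an estimated correlation). In preparation 1 the median difference of beta cell genes was 0.46, beside a median of -1.71 for heat shock genes. Of 14 alpha cell genes, 6 were higher and none lower, also adjusted over the list alone, with PTGER3 at 0.65 ± 0.09, LOXL4 at 0.35 ± 0.07 and CRYBA2 at 0.30 ± 0.07 (camera adjusted p = 0.00864, and adjusted p = 0.738 with an estimated correlation). Of 8 delta cell genes, 1 was lower and none higher (none adjusted over the list alone). SST, the somatostatin gene, was at -0.26 ± 0.10 (adjusted p = 0.0666), and at -0.35 without preparation 1 (adjusted p = 0.0033), with camera's adjusted p for the list at 0.509. Of 26 acinar cell genes, which encode digestive enzymes, 16 were lower and none higher (18 lower adjusted over the list alone). CPB1, CPA1 and REG1B were at -0.69 ± 0.13, -0.81 ± 0.16 and -0.74 ± 0.18. Their median change was -0.50 (camera adjusted p = 7.42e-06, and adjusted p = 0.738 with an estimated correlation), and the list's median was above 0 in 2 of the 10 preparations. The camera calls of the insulin secretion, alpha cell and acinar lists were lost without the block for the preparation (adjusted p = 0.166, 0.327 and 0.413), as were the calls of the called genes of these lists and of beta cells named here (PTGER3 had the smallest adjusted p, 0.24).

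**Figure D3:**
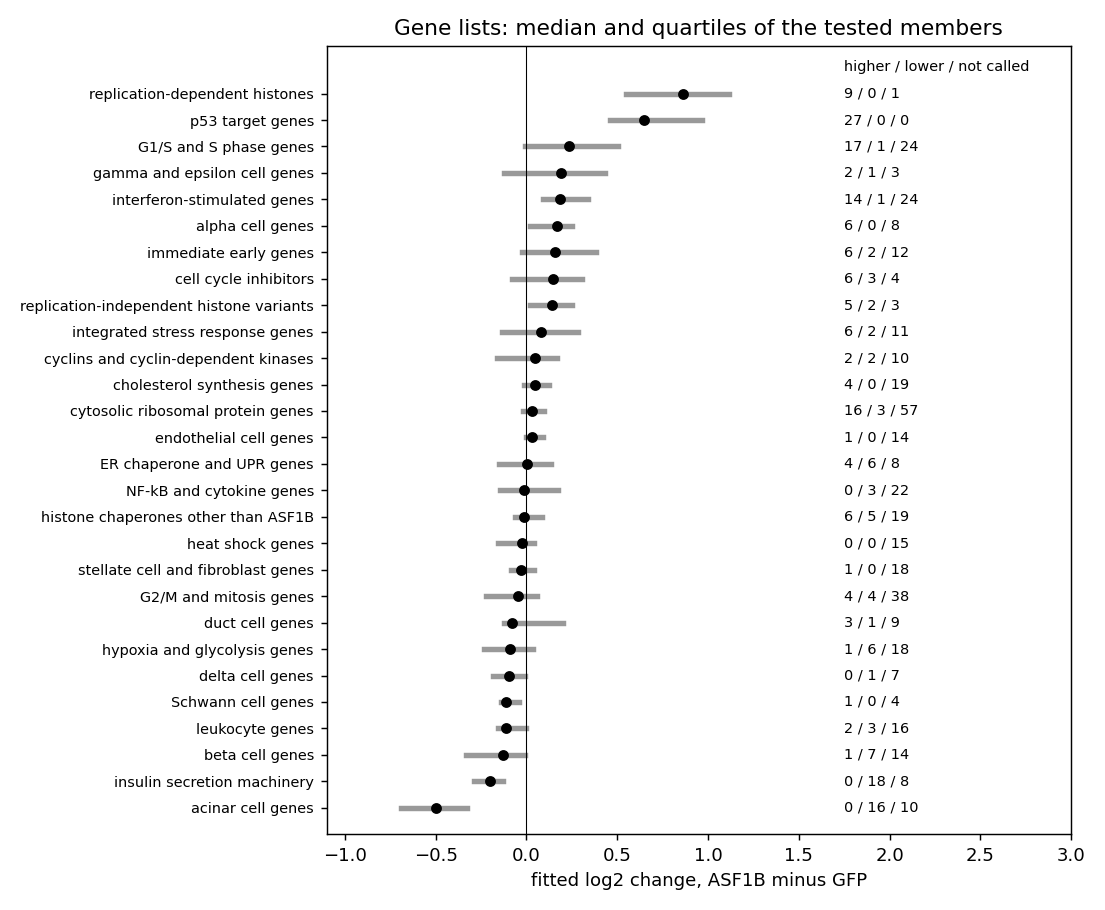
Median (points) and quartiles (bars) of the fitted log2 change, ASF1B minus GFP, over the tested members of each gene list, with counts of members called higher, lower and not called at the right. Replication-dependent histones (median 0.86) and p53 target genes (0.65) lie highest, and acinar cell genes (-0.50) lowest.

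Of 39 interferon-stimulated genes, 14 were higher, 1 lower and 24 not called, also adjusted over the list alone. HERC5 rose by 0.84 ± 0.08, MX1 by 0.46 ± 0.09 and EPSTI1 by 0.35 ± 0.08, and STAT2 was lower at -0.24 ± 0.05. The median change was 0.18 (camera adjusted p = 8.51e-05, and adjusted p = 0.738 with an estimated correlation). The median difference within preparation 10 was 0.89, and it lay between -0.07 and 0.23 in the others. Without preparation 10 the median change was 0.10 (camera adjusted p = 0.00173, and adjusted p = 0.683 with an estimated correlation). Without the block, HERC5, MX1, EPSTI1 and STAT2 lost their calls (adjusted p = 0.0707, 0.437, 0.13 and 0.339). Of 25 NF-kB and cytokine genes, 3 were lower, SOD2, NFKB1 and IER3, and none higher (none adjusted over the list alone, camera adjusted p = 0.986). Their median was -0.01 and their mean 0.04, and the median was 0.02 when libraries were scaled to totals without ASF1B. Leaving out single preparations moved the median between -0.08 (without 4) and 0.12 (without 2). SOD2 lost its call without preparation 3, 6-1 or 10 in turn (adjusted p up to 0.0698), NFKB1 without 2, 5, 6-2 or 10 (up to 0.0735), and IER3 without 1, 2, 3, 5, 6-2, 8 or 9 (up to 0.109). All 3 lost it without the block.

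Across 28 tested lists, camera with the preset correlation of 0.01 called 8, and none were called with an estimated correlation. Swapping the virus labels within preparations gave 8 or more called lists in 86 of 100 splits, the real one included, with up to 17 lists, so this number of called lists is not above that of other splits. Swaps among the 9 donors gave 8 or more in 82 of 90 splits. An exact two-sided sign-flip permutation test of each list over the 10 preparations was chosen after the data were seen. It took the list's mean difference less the median difference of all tested genes in the same preparation. A mean set against a median can lie above 0 through a few members that rise strongly. Schwann cell genes, with a median change of -0.11, stood at 0.13 by this measure (sign-flip adjusted p = 0.0875). After Benjamini-Hochberg adjustment the test called 8 lists. These were cell cycle inhibitors, p53 target genes, replication-dependent histones, alpha cell genes, G1/S and S phase genes and replication-independent histone variants (adjusted p = 0.0182 each), interferon-stimulated genes (0.0312) and insulin secretion machinery (0.041). Acinar cell genes did not pass it (adjusted p = 0.0729). Over the 9 donors it called 7 of these lists (adjusted p = 0.0312 each), and insulin secretion machinery did not pass (adjusted p = 0.0684). Some lists overlap, with 5 pairs of lists sharing a gene. CDKN1A and BTG2, both called higher, belong to the cell cycle inhibitors and to the p53 target genes, so the calls of those lists are not independent.

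**Figure D4:**
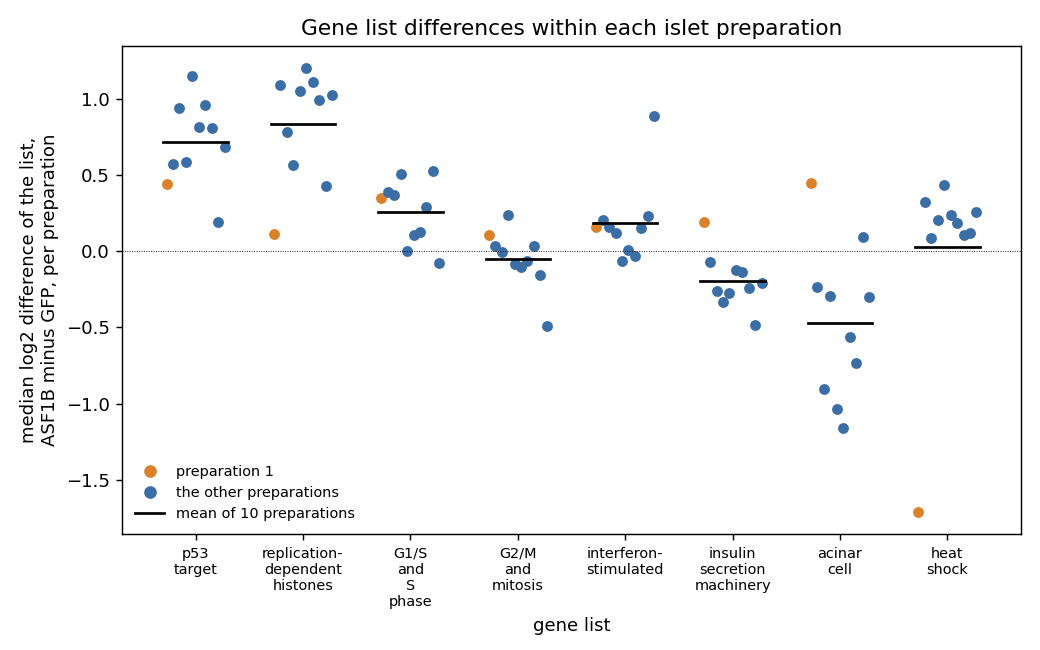
Median log2 difference, ASF1B minus GFP, of 8 gene lists within each of the 10 islet preparations (points, preparation 1 in orange), with the mean of the 10 preparations as a line. The p53 target list is above 0 in all 10 preparations, and heat shock genes in preparation 1 lie at -1.71.

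The last comparison set these calls beside the authors' deposited table of 464 genes, 287 higher and 177 lower in ASF1B. Of these, 421 were tested here, and 420 were called, each with the direction of the authors' deposited table. Independent lists of these sizes would share 143.4 genes, but both rest on the same libraries. A further 4401 genes were called here and are not in the authors' deposited table, whose p-values equal an unpaired 2-sample Student calculation for 464 of its 464 genes, within a relative tolerance of 1e-06.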

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

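The tests of explanations in this part, except the 100 label swaps over preparations, were chosen after the results were seen. Each preparation's difference was compared with those of the other 9, by the gap of the most extreme value to its neighbour over the whole range. Of 166 sets of values, 35 held such a value, where chance gives about 1 in 20 (8.3) for independent sets. These sets were not independent, since lists stood beside their own members and some genes were named after their values were seen. The excess over 8.3 is therefore only descriptive.

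Preparation 1 held 20 of the 35. Its heat shock list had a median log2 difference of -1.71, against 0.09 to 0.43 in the others. Its integrated stress response list was at -0.29, its beta cell list at 0.46 and its delta cell list at 0.46. Its log2 differences stood apart for IAPP (1.12), SLC2A2 (1.34), ADCYAP1 (0.35), SLC30A8 (0.40), GLP1R (0.58), VAMP2 (0.13), ABCC8 (0.32), RGS9 (0.13), LBR (-0.60), DNAJB11 (-0.40), PCDH8 (-1.05), RPL15 (0.21), ZNF554 (-0.20), HSPB1 (-1.71), DNAJA1 (-0.93) and HSPE1 (-1.17). Without preparation 1, 5694 genes were called. Of those other than ASF1B, 49.9% had that fit's sign within preparation 1, against 83.3% to 92.8% for each other preparation compared in the same way. ASF1B itself was higher in its ASF1B library. Without preparation 1, the heat shock list passed camera with a median of 0.21 (adjusted p = 2.58e-05, and adjusted p = 0.421 with an estimated correlation). HSPB1, DNAJA1 and HSPE1 were then higher by 0.78, 0.25 and 0.27.

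Preparation 10 held 5. ASF1B reached 159 in its GFP library, which made its ASF1B difference 11.73, and its ASF1B library was the deepest at 24020836 expected reads. Its interferon list had a median of 0.89 and MX1 a difference of 1.37. The rest were scattered. Preparation 9 stood apart for CAMK1G (-3.23) and G2E3 (-0.73), preparation 5 for MCM7 (1.17), KRT19 (1.00), TPSB2 (2.96) and ASNS (-0.83), preparation 2 for CRYBA2 (1.02) and the NF-kB and cytokine list (-1.01), preparation 3 for PCNA (1.22) and preparation 6-1 for SERPINI2 (-2.72).

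Chance as the source of the number of called genes is argued against, with 1 exception among the swaps. In 100 randomly drawn within-preparation swaps of the virus labels, the real one included, 1 gave as many genes, the real labels with 4821, and the highest of the others gave 3. None of those drawn exchanged 1 preparation alone. Exchanging preparation 1 alone gave 4874 genes, more than the real labels, of which 3842 were also called with the real labels, while exchanging each other preparation alone gave 0 to 1329. This points to a structure of the samples in which preparation 1 differs from the rest. The column headers of preparation 1 also follow another pattern than the rest, and among the rest the GFP and ASF1B headers differ in pattern. What these headers reflect is not given. Over 9 donors, 1 of 90 splits gave as many genes, the real one with 4264, and the highest others gave 4201 with preparation 1 alone exchanged and 356 without that split. For the number of called lists chance was not excluded. Of the 100 swaps, 86 gave as many lists as the real 8, and the highest of the others gave 17. Over 9 donors 82 of 90 gave as many.

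The rise of p53 target genes was not removed by any of 5 scalings, of which the lowest list median was 0.6471, so it does not depend on the choice among them. The scaling that moved genes most, totals without ASF1B, moved them by a median of 0.0304. None of the 5 could therefore have removed a rise of this size, and a larger error of scaling was not tested. Over 9 donors the list's difference correlated with the ASF1B level at r = 0.7203 (exact permutation p = 0.0279, adjusted 0.0558 over 2 relations) and rho = 0.633 (exact permutation p = 0.0760, adjusted 0.121). Without the 2 donors farthest from the median ASF1B level, r was 0.19, so the relation rests on those donors, while without preparation 1 it was 0.90. With the interferon list r was -0.2818 (exact permutation p = 0.448, adjusted 0.448) and rho -0.567 (p = 0.121, adjusted 0.121, exact permutation), and -0.61 without the 2 farthest. An effect of the ASF1B protein and a stronger response to its virus cannot be told apart, because virus and gene came together in every ASF1B library and no virus dose is used here.

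Of acinar cell genes 16, and of beta cell genes 7, were lower. The sign-flip test of lists did not call beta cell genes (adjusted p = 0.222, and 0.308 over 9 donors). A smaller share of those cells in the ASF1B portions would lower alike the genes made only in those cells. The 25 acinar genes with a mean of at least 100 had changes from -0.998 for PNLIPRP1 to -0.17 for KLK1, which was not called, and an exact sign-flip test for unequal changes gave p = 0.049 (0.0195 without preparation 1, 0.0977 over 9 donors). With voom, PNLIPRP1 was at -0.55, and the 25 genes lay between -0.63 and 0.08. Because the test does not pass over 9 donors, a smaller share of acinar cells and a change in the cells cannot be told apart. The 22 beta cell genes changed unequally by the same test (p = 0.0039, and 0.0039 both without preparation 1 and over 9 donors). Their changes ran from -0.64 for IAPP to 0.35 for SLC2A2. A smaller share of beta cells could also lower them unequally if other islet cells make some of these genes, which was not tested. For beta cell genes too, a smaller share of the cells and a change in the cells cannot be told apart.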

How the results depend on the processing

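TMM factors, pseudocounts of 0.5 and 10, robust moderation and the sign-flip test were chosen after the data were seen, as were further alternatives for the lists and the overlap. The number of called genes stayed within 1.5 times of 4821 under all alternatives run except 2. Without the replicate block it was 496 (300 higher, 196 lower), since differences between preparations then count as spread, and at an adjusted p under 0.01 it was 2695 (1238 higher, 1457 lower). All 496 were among the 4821. Of the named genes called with the block, 98 lost their call without it and 38 kept it. Scaling to totals without ASF1B gave 4706 genes, 57.0% of them higher against 45.2%. Leaving out each preparation gave 4077 to 5694 genes, an ASF1B change of 14.72 to 15.22, 8 to 11 lists and an overlap of 419 to 421. Camera called 8 lists, 5 without the block and 0 with an estimated correlation, also without any one preparation (lowest adjusted p = 0.298), and fry called 5. The sign-flip test also called 8, though not the same lists, and over 9 donors 7. Overlap with the authors' deposited table was 264 of 265 tested genes at a PPDE of 1, against 420 of 421 at 0.95 or above, and was highest, 463, with no filter. The ASF1B change lay between 14.26 and 15.22 under every alternative run. Of named genes with leave-one-out losses, calls were also lost with totals without ASF1B (CDAN1, NAP1L1, SOD2, NFKB1, IER3, EGR3, ASNS, RPL22, RPL15 and AIF1, adjusted p = 0.0554 to 0.109), with 9 donors (ADM, AIF1, CKS2, EGR3, NAP1L1, RPL15, RPL22 and TPSB2, 0.0533 to 0.0939), with no filter (AIF1, ASNS, EGR3, IER3, KRT7, RPL15 and TPSB2, 0.0534 to 0.0693) and with upper quartile factors (AIF1, IER3 and RPL15, 0.0501 to 0.0624). ADM, FGB and RFPL2 lost theirs with voom, ADM, AIF1 and IER3 with robust moderation, AIF1 and TPSB2 with a pseudocount of 0.5 and IER3 with TMM factors. ASF1A passed with totals without ASF1B (0.034) and upper quartile factors (0.0498), and camera with the preset correlation called beta cell genes (0.0423) and cholesterol synthesis genes (0.0418) with those totals, and beta cell genes with no filter (0.033). With an estimated correlation these were not called (adjusted p = 0.871 and 0.816 with those totals, and 0.847 with no filter). No called gene or list named in the text changed sign under any alternative run. The cause of the differences for which none is given was not tested. The DESeq2 and edgeR alternatives written beforehand were not run, because the deposited values are a normalized unit. Expected counts were recovered from them for voom, so rounding these for a count model was possible and was not tried. Depth limits the genes below the filter.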

Other observations

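The tests on neighbouring genes, detected genes and developmental transcription factor genes, camera with an estimated correlation for left-out preparations or other scalings, and camera with totals without ASF1B were chosen after the results were seen. Of 20 immediate early genes, 6 were higher and 2 lower (8 and 3 adjusted over the list alone), with FOSL1 at 1.29 ± 0.27, JUNB at 0.47 ± 0.08 and the lower ones EGR1 at -0.37 ± 0.09 and EGR3 at -0.40 ± 0.14. Camera's adjusted p was 0.0703, and 0.0201 and 0.0258 without preparation 1 or 2 (adjusted p = 0.643 and 0.688 with an estimated correlation). Of 19 integrated stress response genes, 6 were higher, among them PPP1R15A at 0.77 ± 0.15, and 2 lower, SLC7A5 at -0.40 ± 0.08 and ASNS at -0.19 ± 0.07, also adjusted over the list alone (camera adjusted p = 0.135, and 0.0308 without preparation 1, where adjusted p = 0.514 with an estimated correlation). ASNS was at -0.12 without preparation 5 (adjusted p = 0.0565). Endoplasmic reticulum chaperone and unfolded protein response genes had 4 higher, CALR (0.24 ± 0.04), DNAJB11, MANF and SEC61B, and 6 lower, such as EDEM1 (-0.24 ± 0.05), of 18, also adjusted over the list alone (camera adjusted p = 0.878). Cholesterol synthesis genes had 4 higher of 23, among them HMGCS1 (0.36 ± 0.05), FDPS and INSIG1, also adjusted over the list alone. Camera's adjusted p was 0.0683, and 0.0255, 0.0478, 0.00998 and 0.0412 without preparation 3, 4, 5 or 6-1 (adjusted p = 0.666 to 0.893 with an estimated correlation). Hypoxia and glycolysis genes had 6 lower, such as VEGFA (-0.32 ± 0.07) and ENO2 (-0.36 ± 0.07), and 1 higher, ADM (0.48 ± 0.15), of 25, also adjusted over the list alone (camera adjusted p = 0.326). Of 76 cytosolic ribosomal protein genes, 16 were higher, such as RPS19 (0.48 ± 0.05), and 3 lower, RPL34 (-0.23 ± 0.04), RPL22 and RPL15 (8 and 1 adjusted over the list alone), with camera's adjusted p at 0.023, and an adjusted p = 0.882 with an estimated correlation. That call was also lost without preparations 1, 2, 5 or 10 in turn (adjusted p = 0.105, 0.0939, 0.0891 and 0.0776). Leaving out single preparations ended the calls of EGR3 (2, 3, 4, 5, 6-1, 6-2 or 9, adjusted p up to 0.105), ASNS (2, 3, 5, 6-1, 8 or 9, up to 0.0712), RPL15 (any except 1, up to 0.0997), ADM (4, 5, 6-1, 6-2 or 10, up to 0.0641) and RPL22 (3, 4, 5, 6-1, 9 or 10, up to 0.0818). The median of the ribosomal list was 0.03, 0.02 without preparation 1 or 2, and 0.06 when libraries were scaled to totals without ASF1B (adjusted p = 0.0021, and adjusted p = 0.871 with an estimated correlation). Without the block for the preparation, PPP1R15A and RPS19 kept their calls, and the other genes named in this paragraph lost them.

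Lists of other cell types gave no camera call (adjusted p from 0.46 to 0.988). Duct cell genes had 3 higher, KRT19 (0.38 ± 0.07), CA2 and KRT7, and 1 lower, AQP1, of 13, also adjusted over the list alone, with a median of -0.08 and a mean of 0.04. Gamma and epsilon cell genes had 2 higher, ETV1 and FGB, and 1 lower, MEIS2, of 6 (3 and 1 adjusted over the list alone). EGFL7 (0.37 ± 0.08) was the 1 higher of 15 endothelial cell genes and ACTA2 (0.39 ± 0.09) the 1 higher of 19 stellate cell and fibroblast genes, also adjusted over each list alone. The stellate list had a median of -0.03, and 0.00 when libraries were scaled to totals without ASF1B. Leukocyte genes had 2 higher, CD68 and TPSB2, and 3 lower, CD163, CD14 and AIF1, of 21 (1 and 2 adjusted over the list alone). Schwann cell genes had 1 higher of 5, also adjusted over the list alone, with a median of -0.11 and a mean of 0.12. TPSB2 was at 0.67, and at 0.42 without preparation 5, and KRT7 at 0.20, and at 0.13 without preparation 5. Leaving out single preparations ended the calls of KRT7 (2, 4, 5, 8, 9 or 10, adjusted p up to 0.0905), AQP1 (4, 0.0513), FGB (4, 5, 6-2 or 10, up to 0.06), TPSB2 (2, 3, 6-1 or 6-2, up to 0.0785) and AIF1 (2, 4, 5, 6-1, 8, 9 or 10, up to 0.125). Without the block, every gene of these lists named here lost its call. None of 15 heat shock genes was called by limma with all preparations (1 at an unadjusted p under 0.05), also adjusted over the list alone (camera adjusted p = 0.878, median -0.03), and the median was 0.01 when libraries were scaled to totals without ASF1B.

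Neighbouring genes on chromosome 19 rose together. In the gene order of GRCh38.p14, the run of 7 tested genes SLC39A3, SGTA, THOP1, ZNF554, ZNF555, ZNF57 and ZNF77 had the highest median statistic of any run. Their changes were 0.27 ± 0.07, 0.79 ± 0.08, 0.63 ± 0.09, 0.73 ± 0.11, 1.39 ± 0.13, 1.05 ± 0.10 and 2.08 ± 0.13. Among 1000 random gene orders none held such a run (p = 0.001, the smallest they can give). The run was also chosen anew without each of the 9 donors, and all 9 choices held SLC39A3, SGTA and THOP1. In the donors left out these 3 had mean differences of 0.25, 0.78 and 0.63 (highest exact sign-flip p = 0.00781). The 3 genes were taken from the run of all donors, and each donor left out helped choose the other runs. These values are therefore those of the same 9 donors and give no support independent of the choice. SLC39A3, SGTA and THOP1 are not zinc finger genes, so the rise is not limited to such genes. Reads shared between zinc finger paralogs do not concern these 3, so their values do not test that explanation. For the zinc finger members such sharing cannot be told apart from a rise of each gene, since the median of 473 other ZNF genes, -0.0024, decides neither. A shared local change at this region may be worth a closer look.

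More genes were detected in the ASF1B libraries. After thinning each library without ASF1B to 8886472 expected reads, 209.1 ± 84.5 more genes (SD, n = 10) had a read in ASF1B, with the sign in 10 of 10 preparations (exact sign-flip p = 0.002, the smallest it can give), so a difference in depth is argued against. Over 9 donors the difference was 203.4 genes (exact sign-flip p = 0.00391). Unthinned, the difference was 182.6 genes, with the sign in 7 of 10. A separate hypothesis is that developmental transcription factor genes, which are low in islets, rise as a class. Among genes with a mean of 1 to 50, and leaving out 50 whose rise had prompted the question, the mean log2 difference of 111 such genes was 0.24 and that of 3635 others 0.12. The class exceeded the others by 0.1288 (9 of 10 preparations, exact sign-flip p = 0.0137, and p = 0.0195 over 9 donors). Libraries were not thinned for this comparison, and the class was not matched to the others by level. An effect of depth or level on it was not tested. Of the class 67.6% of genes were higher on average, and of the others 57.7%. That class was written after some of its members had been seen.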
